A study of Mus musculus with 5 samples.

How the data were processed

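The series holds 4 spatial sections and 1 single-cell library from mouse bone that carried metastases of LLC1, a Lewis lung carcinoma line of the mouse, given through the internal iliac artery. The sections were measured with 10x Genomics Visium, in which each barcoded spot of a slide captures polyadenylated RNA from the cells above it. A spot can therefore hold several cells of different types. The dissociated tissue was measured with the 10x Genomics Chromium Single Cell 3′ assay. All 5 samples carry the same batch label, and the labels do not say which sections share an animal.

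The authors deposited UMI counts per gene and spot for each section, and UMI counts per gene and cell for the dissociated library. Per the submitters' processing notes, Space Ranger 2.1.0, Cell Ranger 7.1.0 and Seurat were used, and the builds mm10 and GRCm38 are named. The headers of some section files name other releases of these programs, so the release behind each deposited count is uncertain. The authors also deposited normalized values for section 1, which match the natural log of 1 plus counts scaled to the same total in every spot, and batch-integrated values for sections 2 to 4, which lie partly below 0. These batch-integrated values were not used as expression. Deposited tables give a cluster number and a name (Tumor, MSCs, Distantial Tissue or Others) for each spot, and a cluster and a class name for each cell. How the spot names were made is not given in the sources used here. The deposited mitochondrial percent of every cell is 0, although 13 mitochondrial genes are in the matrix and hold 0.877% of its UMIs, so this percent was recomputed from the counts. Genes are given by the symbols that the deposited feature tables pair with Ensembl identifiers, and no coordinates were used.

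The sections held 2212, 1869, 2022 and 2153 spots over tissue, with totals between 18589443 and 35467667 UMIs. Only spots over tissue entered the comparisons. UMIs were summed per section and spot class, and the section was the replicate. The classes followed the deposited names. Because the labels give no contrasting groups, every spatial comparison is within sections, with the section as a block. The p-values therefore speak only of these sections, and sections of 1 animal would vary less than animals do.

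The comparison of Tumor-named with Distantial-named spots, the comparison of spots touching a Tumor-named spot with spots more than 3 grid steps from any, the 27 cell lists, the 15 pathway lists, the rule for naming genes and the alternatives to each of these were fixed before the data were examined. So was a panel of 10 genes for LLC1 carcinoma cells (Krt8, Krt18, Krt7, Krt19, Hmga2, Tm4sf1, Fosl1, Areg, Ereg and Ptges), to be used in place of the names. With it, each spot received the panel's share of its UMIs pooled over the spot and its touching neighbours. The 25% of spots in a section with the highest share (panel-high) were compared with the 25% with the lowest (panel-low), and spots touching panel-high spots with spots more than 3 steps away. Reporting these panel comparisons in full, and the comparison of MSCs-named with Distantial-named spots, was decided after the names had been seen. Panel genes chose the spots and were left out of every count and list. A section entered only with at least 20 spots in each class for the touching spots, and with any number otherwise.

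Genes were tested with edgeR 4.0.16 (R 4.3.3), with TMM normalization, filterByExpr at its count minimum of 10, and quasi-likelihood F tests with Benjamini-Hochberg adjustment at 0.05. For the Tumor-named comparison edgeR took the spread as common to all genes (its prior degrees of freedom were infinite), so the smallest p-values of that comparison rest on this assumption. In the other comparisons the prior degrees of freedom were 9.38 to 16.12, against 3 residual ones, or 1 beside Tumor-named spots. All p-values and standard errors thus rest mostly on a spread borrowed across genes. The standard error of a log2 fold change is its size divided by the square root of its F. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at the preset correlation of 0.01 on voom values of the same sums, with Benjamini-Hochberg adjustment over the lists of a comparison. They were tested again with an estimated correlation and with fry. CPM values are means over sections of each section's sum. Alternatives were DESeq2 1.42.0, DESeq2's size factors in edgeR, no filter on low counts, no block, the larger of the 2 sums of a section thinned to the total of the smaller, each section left out in turn, no pooling over neighbours, other bounds for the classes, and deposited clusters in place of the names. The skeletal muscle genes were also left out, which was chosen after seeing the data.

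The rule named the 5 genes with the highest and the 5 with the lowest log2 fold change among called genes of at least 50 CPM that had the same sign in every section, and in each called list the 2 members with the smallest p. Mitochondrial, ribosomal-protein, immunoglobulin-segment and unnamed genes were left out of the first part. For the single-cell library it named the 2 members of each pathway list with the highest CPM. For the comparison of the dissociated library with the sections it named the member of each cell list with the highest section mean. Some genes that the rule picks are not reported here. Leading genes of clusters and classes are given to say what a region or class holds.

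The tests were tested on simulated data drawn from the real sums, in which 100 genes were changed by 2 times and 100 by 4 times. For the Tumor-named against Distantial-named design, 47 of the first and 90 of the second were recovered among 9609 genes, with 3 false calls. With no gene changed there were 0 edgeR calls among 9546 genes. The simulated counts were drawn with the spread that edgeR had estimated from the real sums, and few genes were changed. These numbers therefore test neither that estimate nor the normalization.

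Cell shares of the single library have exact Clopper-Pearson 95% intervals, and CPM values within it exact Poisson intervals. Both cover counting error only, and no test was made with 1 library. The deposited matrix held 14992 cells with 500 to 12894 UMIs and 201 to 2499 genes each, and no further cell was removed. Cells outside these ranges may have been left out before deposition. Scrublet, run through scanpy 1.11.5, marked 1 cell (0.00667%) at its automatic bound, so its call was not used, and leaving out the 5% of cells with the highest scores took its place. Cells were also clustered anew with the Leiden method on 2000 variable genes, 30 components and 15 neighbours at resolution 1, and each cluster was scored against the fixed lists. Values shared between the dissociated library and the sections were set over the 22774 gene symbols in both.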

Results

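Mouse bone bearing LLC1 metastases was profiled as 4 Visium sections and 1 dissociated single-cell library. The sections held 2212, 1869, 2022 and 2153 spots over tissue, 8256 in all. Sections 1 to 4 gave 35467667, 26505569, 25006372 and 18589443 UMIs, with medians of 11979.5, 9785, 9602.5 and 4988 UMIs per spot. Section 4 was thus the shallowest. Mitochondrial transcripts made up 4.53%, 2.96%, 3.16% and 3.74% of UMIs in the 4 sections. Summed counts of any 2 sections differed by more than sampling noise, with a chi-square per gene of 44.1 to 259, so no section was a copy of another. Erythroid transcripts were highest in section 1, at 86629 CPM over the whole section against 22286 to 37143 CPM in the other sections.

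The spots deposited as Tumor lay mostly over skeletal muscle transcripts. Of the 299 Tumor-named spots, 234 (78.3%) fell in deposited cluster 1, which was led by Ampd1, Myh1, Myl1, Cox8b and Atp2a1, genes of muscle contraction and muscle energy metabolism. Another 51 (17.1%) fell in cluster 3, led by the matrix genes Tnn, Postn, Col8a2 and Ostn. Of the 424 MSCs-named spots, 341 (80.4%) fell in cluster 3. Of the 1370 spots named Distantial Tissue, 568 (41.5%) fell in cluster 0 and 385 (28.1%) in cluster 2, both led by genes of red cell precursors such as Hbb-bt. Cluster 7, led by the cartilage genes Snorc, Col27a1 and Col9a1, and cluster 6, led by the neutrophil genes Wfdc21, S100a9 and S100a8, were named Others for the greatest part.

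The fixed LLC1 panel was highest in cluster 10, at 359 ± 98.2 CPM (SD, n = 4 sections), against 88.4 ± 39.3 CPM in the Tumor-named, 159 ± 80.7 CPM in the MSCs-named, 106 ± 53.6 CPM in the Others-named and 29.2 ± 13.2 CPM in the Distantial-named spots. Much of the panel's CPM came from Tm4sf1. In the Tumor-named spots of sections 1 to 4 it gave 41.6 of 54.0, 22.9 of 54.7, 103 of 120 and 89.4 of 124. In the MSCs-named it gave 49.1 of 65.0, 183 of 257, 112 of 134 and 115 of 179. In cluster 10 it gave 120 of 267, 224 of 479, 119 of 292 and 150 of 400. Since Tm4sf1 was also highest in the Endothelial class of the dissociated library, these levels do not measure LLC1 cells alone. Of the Tumor-named spots of sections 1 to 4, 69 of 164, 6 of 50, 5 of 5 and 29 of 80 were among the 25% of spots with the highest panel share, against 51.3% to 71.3% of the MSCs-named, 25.1% to 27.4% of the Others-named and 3.02% to 6.57% of the Distantial-named spots. Cluster 10 held 309 spots, of which 286 were named Others, 22 MSCs and 1 Tumor. It was led by Prkg2, Ptn, Rhox5, Ccl2 and Hmga2, followed by the interferon-induced chemokines Cxcl9 and Cxcl10 and by S100a4 and Ccl5. Its skeletal muscle list stood at 464 ± 53.1 CPM, against 56121 ± 18409 CPM in the Tumor-named spots.

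**Figure D1:**
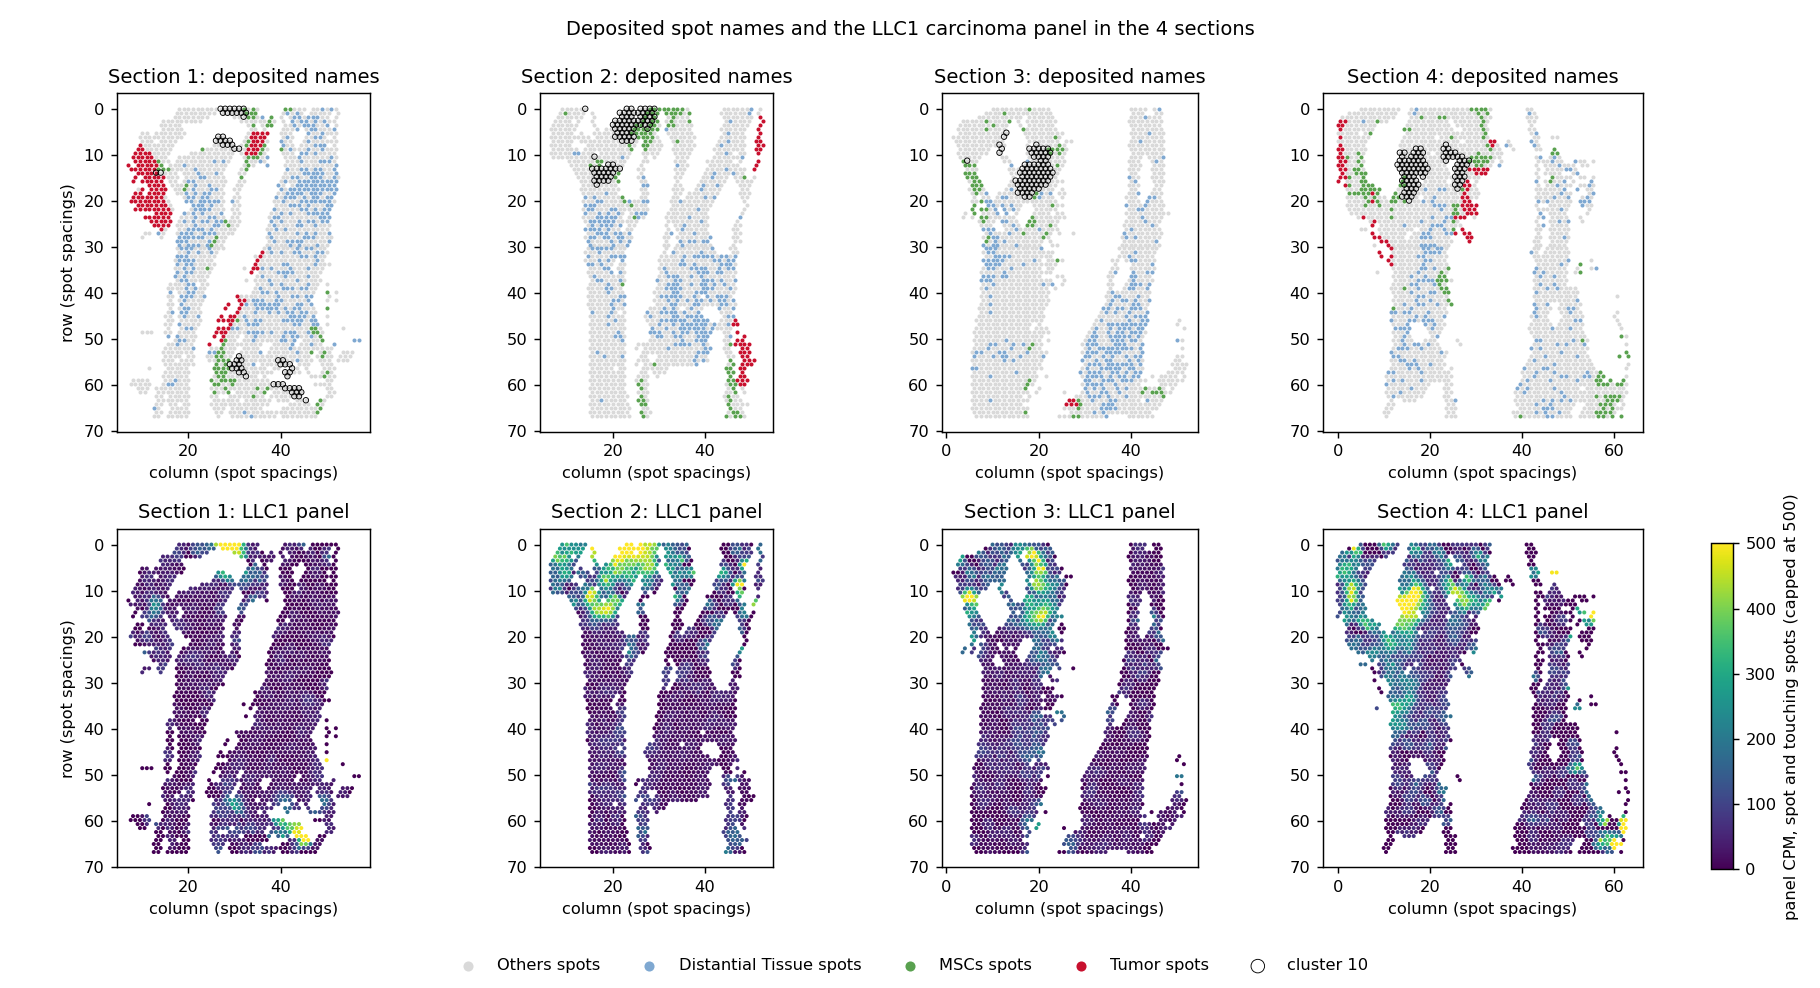
Each point is a Visium spot at its row and column on the slide, in spot spacings, for sections 1 to 4. The upper maps are coloured by deposited name, with open circles on the 309 spots of cluster 10, and the lower maps by the LLC1 panel's CPM pooled over a spot and its touching neighbours, capped at 500 CPM, so that the bright patches can be set beside the Tumor-named spots.

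The first comparison asked which genes set Tumor-named spots apart from Distantial-named spots of the same section. Genes of the muscle fibre stood furthest apart. Myh1, a fast myosin heavy chain, averaged 2908 CPM in the Tumor-named and 21.45 CPM in the Distantial-named sums, a log2 fold change of 6.88 ± 0.41 (SE, n = 4 sections). Mb, the oxygen store myoglobin, rose by 6.86 ± 0.42, Cox8b, a muscle subunit of cytochrome c oxidase, by 7.30 ± 0.37, and Sypl2 by 6.88 ± 0.32. Genes of red cell precursors fell: Tent5c by 1.84 ± 0.32 and Hemgn by 1.76 ± 0.28 on the log2 scale. Pabpc1, a poly(A)-binding protein, fell by 1.80 ± 0.34 and Hmgb2, a chromatin protein of dividing cells, by 1.78 ± 0.32. All 8 genes moved the same way in all 4 sections, with edgeR adjusted p from 5.4e-97 for Sypl2 to 1.67e-06 for Pabpc1.

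Of the 35 lists tested, 9 were higher and 6 lower in Tumor-named spots by camera. For each of the 15, adjusted p = 0.399 with an estimated correlation, so that camera then called 0 lists. All 8 members of the skeletal muscle list rose, Tnni2, a fast troponin, by 6.56 ± 0.43 (camera adjusted p = 3.39e-14). In spots so rich in muscle transcripts, 6 of 7 fibroblast members rose (Clec3b 5.14 ± 0.36, Fbln1 3.46 ± 0.27), as did 11 of 12 matrix remodelling members (Postn 2.82 ± 0.29, and Mmp2, a gelatinase, 2.26 ± 0.27). The pericyte and smooth muscle list rose in 3 of 3 members (Rgs5 3.50 ± 0.25, Acta2 2.22 ± 0.29) and the adipocyte list in 3 of 3. Of the latter, Car3, a carbonic anhydrase of fat and also of muscle fibres, rose by 5.54 ± 0.37, and Cfd, or adipsin, by 3.71 ± 0.34. Of the Schwann cell list, 2 of 3 members rose, the myelin gene Pmp22 by 3.49 ± 0.26. The hypoxia and glycolysis list rose in 6 of 10 members, among them Bnip3, a mitophagy gene, at 2.70 ± 0.26 and the hexokinase Hk2 at 1.88 ± 0.24. The endothelial list rose in 4 of 8 members (5 adjusted over the list alone), with Flt1 at 1.74 ± 0.30 and Egfl7 at 1.00 ± 0.27. The immediate early list rose in 4 of 8 (5 adjusted over the list alone), with the nuclear receptor Nr4a1 at 3.15 ± 0.26 and the heat shock gene Hspa1a at 4.76 ± 0.56.

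The lists that fell in Tumor-named spots belong to the marrow. All 10 proliferation members fell, Cenpf, a kinetochore protein, by 1.63 ± 0.27 and the mitotic kinase Aurkb by 1.27 ± 0.28 on the log2 scale. Of the erythroid list 7 of 8 members fell (8 adjusted over the list alone), the beta globin Hbb-bt by 1.56 ± 0.40. Immature neutrophil genes fell in 6 of 8 members, with the collagenase Mmp8 at −1.55 ± 0.31 and the transcription factor Cebpe at −1.14 ± 0.28. Mature neutrophil genes fell in 7 of 8, with the receptors Csf3r at −1.06 ± 0.27 and Cxcr2 at −0.92 ± 0.26. The megakaryocyte and platelet list fell in 5 of 6 members (6 adjusted over the list alone; Ppbp −1.29 ± 0.30, Gp1bb −0.87 ± 0.26). The B cell list fell in 5 of 7 (6 adjusted over the list alone), with Pax5, the B lineage factor, at −1.44 ± 0.29 and Ms4a1 at −1.11 ± 0.30. For every other called list of this comparison the counts over all genes and adjusted over the list alone were the same.

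Over all genes, edgeR called 1936 of 10040 tested genes higher and 1443 lower (n = 4 sections; 5 to 164 Tumor-named and 246 to 457 Distantial-named spots per section; sums of 58131 to 8847603 UMIs). Camera adjusted p of the 15 called lists reached up to 0.0341 for the endothelial list. With the estimated correlation 2 lists had an unadjusted p under 0.05. Fry called 12 lists, 9 of them among the 15, and did not call the immature neutrophil, erythroid, megakaryocyte, B cell, proliferation and matrix remodelling lists. Section 3 entered with only 5 Tumor-named spots. Without section 2, 825 genes were lower. Scaling by DESeq2's size factors gave 1777 higher and 1977 lower genes and moved the median log2 fold change of all genes from −0.05 to −0.15. With panel-high against panel-low spots, described below, in place of the names, 29 of 35 values of named genes kept their direction and call, 5 lost the call and Hk2 turned (−0.12). Between the clusters with the highest and the lowest panel share 21 of 32 kept both, and those that turned were −0.73 for Cox8b, −0.82 for Myh1, −1.04 for Mb, −0.90 for Tnni2, −0.76 for Cfd and −0.43 for Hk2.

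**Figure D2:**
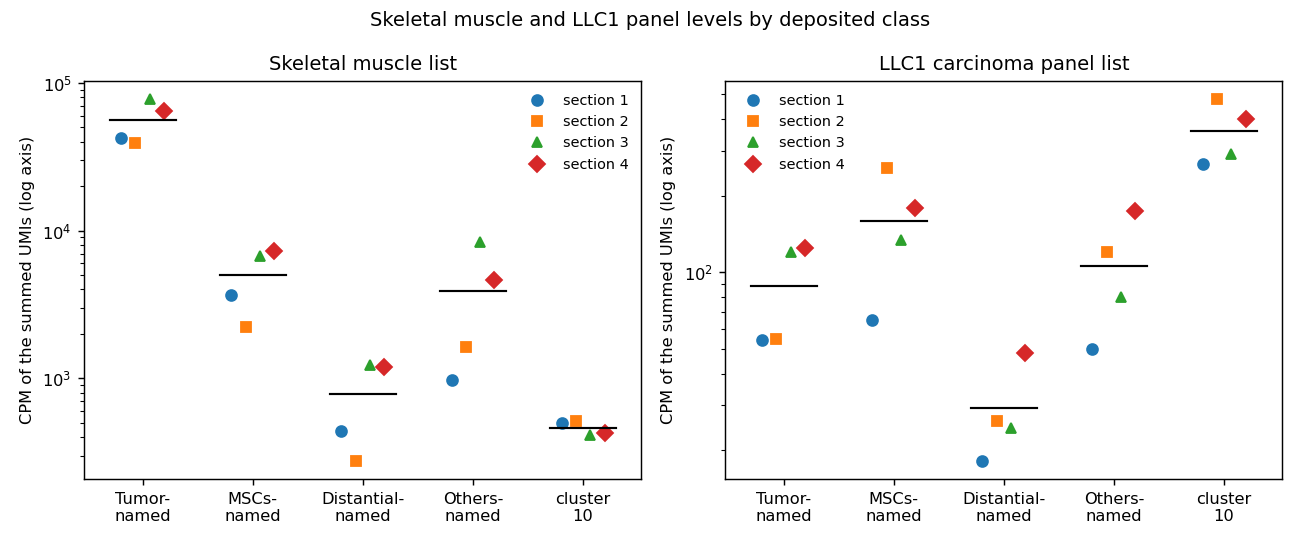
CPM of the summed skeletal muscle list (left) and of the LLC1 panel (right) on log axes, by deposited name and for cluster 10. Each marker is 1 section and each bar the mean of 4. The muscle list is highest in Tumor-named spots (mean 56121 CPM) and the panel in cluster 10 (mean 359 CPM).

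The tissue next to Tumor-named spots was compared with tissue more than 3 steps away, in sections 1 and 4 alone (60 and 92 touching, 1849 and 1778 distant spots), since sections 2 and 3 had 9 and 7 touching spots. The spots touching Tumor-named spots were also rich in muscle transcripts. Myh4, the fastest myosin heavy chain, averaged 2955 CPM in touching and 94.7 CPM in distant spots, a log2 fold change of 4.90 ± 0.25 (SE, n = 2 sections). The calcium-handling genes Trdn, Pvalb and Casq1 rose by 4.88 ± 0.27, 4.79 ± 0.26 and 4.66 ± 0.25, and Myoz1, of the Z-disc, by 4.57 ± 0.25. All 5 had an edgeR adjusted p of 3.17e-08, which rests on 1 residual degree of freedom and mostly on a spread borrowed across genes. The genes that fell most were Rhag, a red cell membrane protein, by 1.33 ± 0.29, Hdc, the histamine-forming enzyme, by 1.22 ± 0.27, Dtl by 1.21 ± 0.25, Rab44 by 1.16 ± 0.28 and Apol11b by 1.12 ± 0.24, with edgeR adjusted p of 0.00615 to 0.0173. All 10 had the same sign in both sections.

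By camera, 7 of 39 lists were higher and 5 lower in the touching spots. For each of the 12, adjusted p = 0.648 with an estimated correlation, and fry called 0 lists (9 at an unadjusted p under 0.05). All 8 skeletal muscle members rose (Tnnc2 4.50 ± 0.24), 6 of 8 fibroblast members (the small proteoglycan Dcn 2.36 ± 0.22, Clec3b 2.60 ± 0.25), 8 of 12 matrix remodelling members (9 adjusted over the list alone; Postn 2.36 ± 0.27, Mmp2 by 2.46 times) and 2 of 5 pericyte members (4 adjusted over the list alone; Rgs5 1.64 ± 0.22, Myh11 1.89 ± 0.44). The hypoxia and glycolysis list rose in 3 of 13 (4 adjusted over the list alone; Bnip3 1.44 ± 0.33, Hk2 1.04 ± 0.25) and the immediate early list in 4 of 10 (5 adjusted over the list alone; Jun 1.46 ± 0.24, Nr4a1 1.72 ± 0.28). Of the Schwann cell list Pmp22 rose by 2.05 ± 0.22 (1 of 5 members, 2 adjusted over the list alone). Proliferation members fell in 3 of 10 (9 adjusted over the list alone; Cdk1 −0.88 ± 0.25, Top2a −0.81 ± 0.23), immature neutrophil members in 3 of 8 (7 adjusted over the list alone; Mmp8 −1.08 ± 0.26, Camp −0.91 ± 0.24) and mature neutrophil members in 2 of 8 (5 adjusted over the list alone; the alarmins S100a8 −0.97 ± 0.23 and S100a9 −0.94 ± 0.23). The erythroid list was called lower with 0 of 8 members called by edgeR, over all genes or adjusted over the list alone (Slc4a1 −0.61 ± 0.24, Alas2 −0.55 ± 0.24). The plasma cell list was called lower with 0 of 5 (3 adjusted over the list alone; Igha −0.70 ± 0.23, Jchain −0.72 ± 0.24).

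Over all genes, edgeR called 901 of 13372 tested genes higher and 103 lower, from 2 sections only. The number lower varied most: 26 by DESeq2, 189 with its size factors in edgeR, 578 with no filter on low counts, 44 when touching meant within 2 steps and distant beyond 5, which also let section 2 enter, and 37 after thinning, which left 488 higher. Without the block edgeR called 0 genes either way, with 1376 at an unadjusted p under 0.05. With the estimated correlation camera called 0 lists, also at an unadjusted p under 0.05. Around the panel-high spots, described below, S100a8 stood at 0.14, Igha at 0.20 and Jchain at 0.06 on the log2 scale.

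The 25% of spots highest in LLC1 panel share (panel-high) were then compared with the 25% lowest (panel-low) of the same section, which sets the classes without the deposited names. Cluster 10 gave 60, 82, 75 and 85 of the panel-high spots of sections 1 to 4. Cluster 3, of matrix genes, gave 134, 96, 100 and 131. Cluster 7, of cartilage genes, gave 72, 158, 126 and 56, and cluster 1, of muscle genes, 69, 70, 63 and 99. The class thus mixes tissues, and what rises in it cannot be put down to LLC1 cells alone. The panel genes that set these classes apart, and are no result themselves, were Tm4sf1 (means of 118 and 3.27 CPM), Hmga2 (54.3 and 0.731), Ptges (39.4 and 1.63), Fosl1 (25.4 and 0.428) and Krt18 (3.90 and 0.514). Of these, Tm4sf1 was also highest in the Endothelial class of the dissociated library, described below. Among all other genes, Rhox5, a homeobox gene of the reproductive tract, averaged 174.5 CPM in panel-high and 10.6 CPM in panel-low spots, a log2 fold change of 4.11 ± 0.29 (SE, n = 4 sections). The growth factor Ptn rose by 3.95 ± 0.28, the interferon-induced chemokine Cxcl9 by 3.37 ± 0.26, and the collagens Col3a1 by 3.16 ± 0.32 and Col18a1 by 3.14 ± 0.24. Red cell genes fell: Slc43a1 by 2.28 ± 0.25, the alpha globin Hba-a2 by 2.23 ± 0.53, Tent5c by 2.18 ± 0.23, Epb41, of the membrane skeleton, by 2.11 ± 0.20 and Rhag by 2.08 ± 0.21. All 10 genes had the same sign in all 4 sections, with edgeR adjusted p from 3.94e-06 to 0.00349. The muscle genes of the previous comparisons did not stand apart here, since 0 of 8 skeletal muscle members were called by edgeR and the list's median log2 fold change was 0.19 (camera adjusted p = 0.651).

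In panel-high spots, 13 of 39 lists were higher and 9 lower by camera. For these 22, adjusted p = 0.358 to 0.469 with an estimated correlation, where camera called 0 lists. Lists of bone, cartilage and connective tissue rose: 10 of 11 osteoblast and osteocyte members (the osteocalcins Bglap2 2.30 ± 0.18 and Bglap 2.17 ± 0.20), 6 of 7 osteoclast members (the acid phosphatase Acp5 2.36 ± 0.25, Atp6v0d2 1.97 ± 0.20), 7 of 7 chondrocyte members (aggrecan Acan 3.04 ± 0.37, Comp 1.66 ± 0.21), 7 of 8 fibroblast members (Dcn 2.39 ± 0.23; 1 fell) and 5 of 5 pericyte members (Acta2 2.05 ± 0.17, Tagln 2.11 ± 0.25). The marrow stroma list was not called by camera (adjusted p = 0.1004) and called lower by fry (adjusted p = 0.0347), with 4 of 7 members lower, 1 higher and a median of −0.60. Matrix remodelling rose in 11 of 12 members (Timp1, a metalloproteinase inhibitor, 2.85 ± 0.25, and the collagen cross-linker Lox 1.78 ± 0.16; 1 fell when adjusted over the list alone). The osteolytic and bone-colonisation list rose in 8 of 10 with 1 lower (collagenase Mmp13 2.44 ± 0.22, osteopontin Spp1 1.99 ± 0.22), and the mesenchymal transition list in 6 of 8 (Twist1 2.72 ± 0.22, Snai1 2.91 ± 0.29). The angiogenesis list rose in 5 of 8 with 1 lower (Vegfc 1.33 ± 0.21, Apln 2.18 ± 0.36). The endothelial list was not called by camera (adjusted p = 0.0683) and called higher by fry (adjusted p = 0.00913), with 5 of 8 members higher (Emcn 1.41 ± 0.22, Cdh5 0.84 ± 0.15).

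Immune lists went both ways. All 6 MHC class II members rose (H2-Eb1 2.52 ± 0.21, H2-Ab1 2.02 ± 0.20), as did 6 of 8 T cell members (Trbc2 2.04 ± 0.17, Trac 2.00 ± 0.22), 6 of 9 immune checkpoint members with 1 lower (Lag3 2.18 ± 0.26, Pdcd1 2.45 ± 0.40) and 5 of 7 monocyte chemoattractants (Ccl8 2.98 ± 0.21, Ccl2 2.88 ± 0.22; 1 fell when adjusted over the list alone). The interferon response (adjusted p = 0.0809), MHC class I (0.411), NK cell (0.169), macrophage (0.169) and monocyte (0.344) lists were not called by camera. Marrow lists fell: the erythroid list in 8 of 8 members (Alas2, of haem synthesis, −1.78 ± 0.21), the megakaryocyte list in 6 of 6 (Gp1bb −1.59 ± 0.20, Itga2b −1.38 ± 0.20), the B cell list in 7 of 7 (Pax5 −1.37 ± 0.21, Cd79b −1.31 ± 0.23) and the early B cell list in 5 of 5 (the surrogate light chain Vpreb1 −1.51 ± 0.22, the recombinase Rag2 −1.42 ± 0.31). Immature neutrophil members fell in 7 of 8 (Mmp8 −1.66 ± 0.24, Cebpe −1.43 ± 0.23), mature neutrophil members in 5 of 8 with 1 higher (Cxcr2 −1.54 ± 0.25, Csf3r −1.23 ± 0.21), progenitors in 6 of 7 (Ms4a3 −1.55 ± 0.23, Prtn3 −1.13 ± 0.22), mast cell and basophil members in 4 of 5 (Prss34 −1.28 ± 0.22, Gata2 −0.90 ± 0.18) and proliferation in 9 of 10 (10 adjusted over the list alone; Cenpf −1.305 ± 0.166, Ube2c −1.34 ± 0.18).

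Over all genes, edgeR called 3332 of 12702 tested genes higher and 3163 lower in panel-high spots (467 to 553 spots per class and section, sums of 1720365 to 8149210 UMIs). Camera adjusted p of the 22 called lists ran from 2.55e-06 (matrix remodelling) to 0.0431 (angiogenesis). With the estimated correlation 2 lists had an unadjusted p under 0.05, and fry called 30, 21 of them among the 22.

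Spots that touched panel-high spots were set against spots more than 3 steps from them. Muscle, cartilage and connective tissue genes were higher at the border. Actn2, of the muscle Z-disc, averaged 93.5 CPM in touching and 9.66 CPM in distant spots, a log2 fold change of 2.99 ± 0.31 (SE, n = 4 sections). Myh2 rose by 2.82 ± 0.42, Mb by 2.82 ± 0.45, Cox8b by 2.59 ± 0.27, and Snorc, a cartilage membrane proteoglycan, by 2.57 ± 0.12. Slc43a1 fell by 1.06 ± 0.18, Epb41 by 1.06 ± 0.10, Tent5c by 1.04 ± 0.13, Rhag by 1.03 ± 0.12 and Hba-a2 by 0.97 ± 0.22 on the log2 scale. All 10 had the same sign in all 4 sections, with edgeR adjusted p from 6.13e-07 to 0.00559.

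At this border 14 of 39 lists were higher and 2 lower by camera. For these 16, adjusted p = 0.304 to 0.515 with an estimated correlation, where camera called 0 lists. All 8 skeletal muscle members rose (Mylpf 2.12 ± 0.21, Acta1 2.29 ± 0.23), 7 of 7 chondrocyte members (Col2a1 1.496 ± 0.115), 10 of 11 osteoblast members (Alpl, the bone alkaline phosphatase, 1.56 ± 0.12, Bglap2 1.78 ± 0.16), 7 of 8 osteoclast members (8 adjusted over the list alone; Acp5 1.73 ± 0.18, Atp6v0d2 1.44 ± 0.15), 7 of 8 fibroblast members (Dcn 2.101 ± 0.111, Clec3b 2.69 ± 0.24), 5 of 5 pericyte members (Rgs5 1.51 ± 0.13, Acta2 1.12 ± 0.18) and 5 of 5 adipocyte members (Cfd 2.24 ± 0.16, Car3 2.01 ± 0.17). Matrix remodelling rose in 11 of 12 (Mmp2 1.75 ± 0.12, Timp1 1.79 ± 0.13), osteolytic and bone-colonisation factors in 5 of 9 (7 higher and 1 lower adjusted over the list alone; Mmp13 1.48 ± 0.14, Ccn2 1.39 ± 0.15), mesenchymal transition in 6 of 8 (Twist1 1.48 ± 0.17, Vim 1.21 ± 0.17) and hypoxia and glycolysis in 6 of 12 with 1 lower (Eno1 1.71 ± 0.19, Bnip3 1.13 ± 0.16). MHC class II members rose in 5 of 6 (H2-Eb1 1.57 ± 0.15, H2-Ab1 1.17 ± 0.13), T cell members in 5 of 8 (Trbc2 1.08 ± 0.17, Trac 1.16 ± 0.20) and monocyte chemoattractants in 4 of 7 (Ccl8 2.25 ± 0.19, Ccl7 1.57 ± 0.35). Erythroid members fell in 7 of 8 (Car1 −0.75 ± 0.10) and proliferation in 8 of 10 (9 adjusted over the list alone; Cenpf −0.78 ± 0.12, Ube2c −0.61 ± 0.10).

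Over all genes, edgeR called 2097 of 12359 tested genes higher and 1637 lower at this border (n = 4 sections, sums of 1593254 to 15270298 UMIs). Without pooling over neighbours it called 211 higher and 5 lower, and without the block 648 and 184. Without section 3 it called 1383 and 742, and without section 2, 977 lower. With the estimated correlation 4 lists had an unadjusted p under 0.05, and fry called 23, all 16 among them.

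The MSCs-named spots were set against Distantial-named spots in the same way. Genes of connective tissue and bone surface stood highest. Tnn, a tenascin of bone and tendon, averaged 406 CPM in MSCs-named and 8.76 CPM in Distantial-named sums, a log2 fold change of 5.34 ± 0.24 (SE, n = 4 sections). Ostn, or osteocrin, rose by 5.21 ± 0.25, Fndc1 by 5.21 ± 0.23, Postn, the matrix protein periostin, by 5.03 ± 0.31, and Aspn, an inhibitor of mineralisation, by 4.96 ± 0.24. Red cell genes fell: Rhag by 1.90 ± 0.22, Hemgn by 1.88 ± 0.22 and Prxl2a by 1.83 ± 0.19. All 8 had the same sign in all 4 sections, with edgeR adjusted p from 7.05e-12 to 1.14e-06. The skeletal muscle list rose with them, 8 of 8 members (Myh1 2.96 ± 0.18, Tnni2 2.82 ± 0.18), from 782 ± 496 CPM in Distantial-named to 4972 ± 2417 CPM in MSCs-named spots (SD, n = 4).

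By camera, 11 of 37 lists were higher and 7 lower in MSCs-named spots. For these 18, adjusted p = 0.376 to 0.493 with an estimated correlation, where camera called 0 lists. All 12 matrix remodelling members rose (Mmp14 3.96 ± 0.22, Mmp2 4.07 ± 0.23), all 11 osteoblast and osteocyte members (Alpl 3.53 ± 0.22, Bglap2 3.16 ± 0.23), all 7 osteoclast members (Atp6v0d2 3.13 ± 0.23, and cathepsin K, Ctsk, 2.65 ± 0.20), all 5 chondrocyte members (Comp 3.84 ± 0.18, Acan 4.61 ± 0.37) and 7 of 8 fibroblast members with 1 lower (Dcn 4.58 ± 0.20, Fbln1 4.03 ± 0.21). Pericyte members rose in 4 of 4 (Rgs5 2.96 ± 0.19, Tagln 4.05 ± 0.36), adipocyte members in 3 of 4 (Car3 2.71 ± 0.19, Cfd 2.16 ± 0.19), the osteolytic and bone-colonisation list in 7 of 8 with 1 lower (Ccn2 3.30 ± 0.19, Mmp13 3.21 ± 0.22), mesenchymal transition in 6 of 7 (7 adjusted over the list alone; Twist1 3.53 ± 0.28, Snai2 3.30 ± 0.28) and MHC class II in 5 of 6 (H2-Eb1 1.70 ± 0.20, H2-Ab1 1.33 ± 0.18). The erythroid list fell in 8 of 8 (Alas2 −1.45 ± 0.20), megakaryocytes in 6 of 6 (Gp1bb −1.27 ± 0.18, Itga2b −1.22 ± 0.19), B cells in 7 of 7 (Ms4a1 −1.47 ± 0.22, Cd79b −1.09 ± 0.20), proliferation in 10 of 10 (Cdk1 −1.26 ± 0.18, Ube2c −1.26 ± 0.19) and progenitors in 6 of 7 with 1 higher (Ms4a3 −1.15 ± 0.21, Prtn3 −0.95 ± 0.20). Immature neutrophil members fell in 7 of 8 (8 adjusted over the list alone; Cebpe −1.23 ± 0.21, Mmp8 −1.34 ± 0.23) and mature neutrophil members in 7 of 8 (Cxcr2 −1.26 ± 0.23, Csf3r −1.05 ± 0.21).

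Over all genes, edgeR called 2810 of 10650 tested genes higher and 2689 lower (n = 4 sections, 76 to 152 MSCs-named spots per section, sums of 910359 to 8847603 UMIs). With the estimated correlation 3 lists had an unadjusted p under 0.05, and fry called 24, 14 of them among the 18. In this comparison and those of the panel-high spots and their border, the counts of the lists called by camera were the same over all genes and adjusted over the list alone except where both are given.

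**Figure D3:**
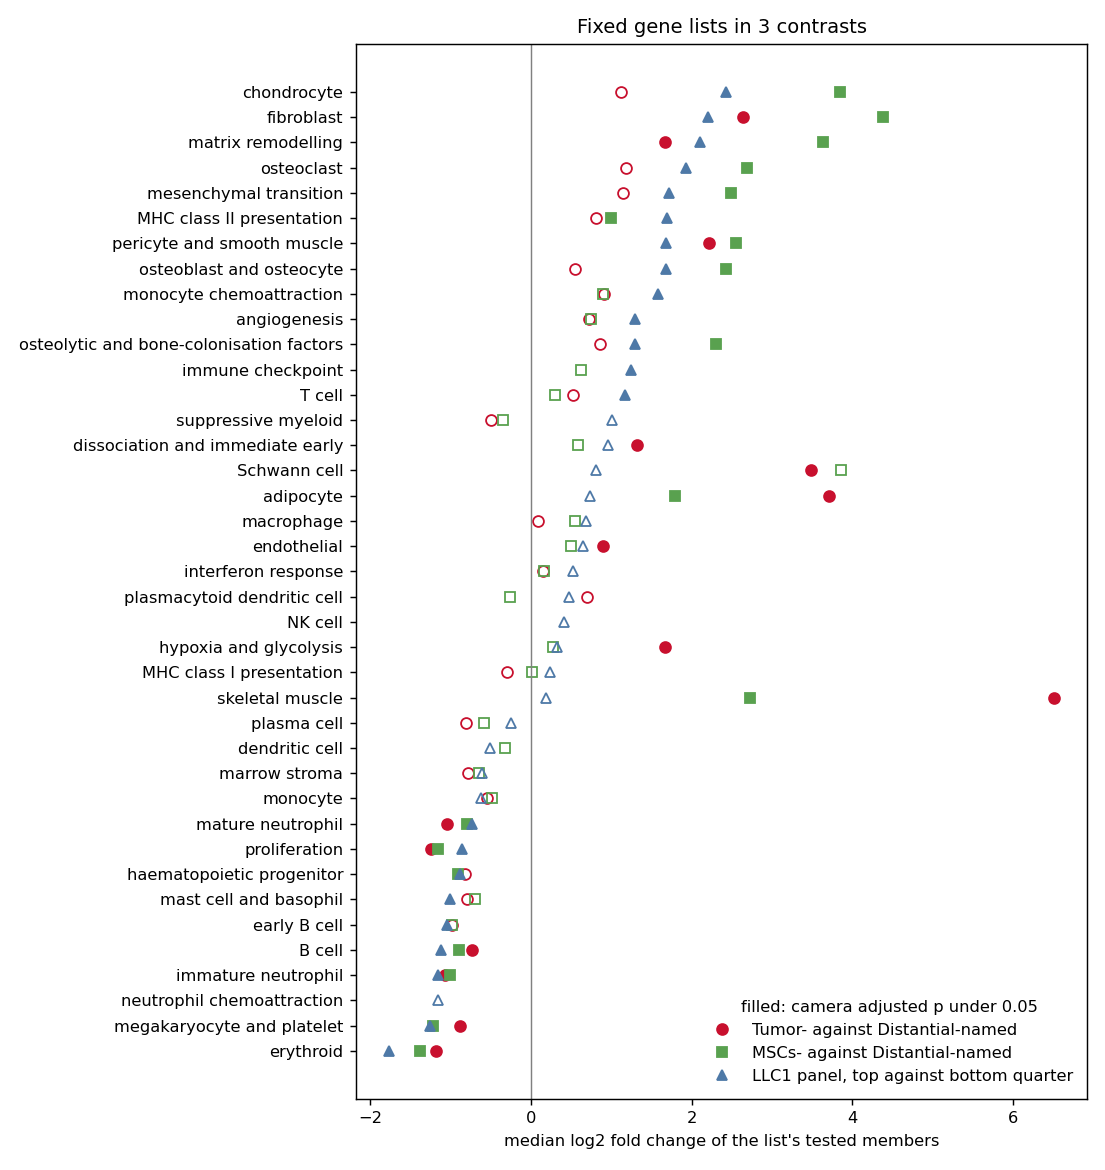
Median log2 fold change of each fixed list's tested members in 3 comparisons: Tumor-named against Distantial-named (circles), MSCs-named against Distantial-named (squares) and panel-high against panel-low spots (triangles), over 4 sections each. Filled symbols have a camera adjusted p under 0.05 at the preset correlation. The skeletal muscle list lies at 6.51 in Tumor-named spots and at 0.19 in panel-high spots.

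The dissociated library held 14992 cells, with a median of 3467 UMIs per cell and 56085966 UMIs in all. Neutrophils and their precursors made up most of it. The class deposited as Myeloid held 8061 cells (53.8%, 95% interval 53.0% to 54.6%), in 6 clusters led by genes such as Stfa2l1 and Cxcr2, Mmp8 and Ly6g, or Fcnb and Elane. The Erythroid class held 2106 cells (14.05%, 13.5% to 14.6%), Macrophage 1406 (9.38%, 8.92% to 9.86%), B cell 1327 (8.85%, 8.40% to 9.32%), plasma B cell 1079 (7.20%, 6.79% to 7.62%), MSCs 352 (2.35%, 2.11% to 2.60%), T cell 306 (2.04%, 1.82% to 2.28%), pre-B cell 272 (1.81%, 1.61% to 2.04%) and Endothelial 83 (0.554%, 0.441% to 0.686%). No class was named for tumour cells.

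For 3 deposited classes the leading genes belong to other cell types than the name. The plasma B cell class was led by Prg2, Epx and Prg3, granule genes of eosinophils, with Prg2 at 3974 CPM against 141 CPM in the next class, and its level of Mpo, a promyelocyte gene, was 1563 CPM. This class also held 111 of the 145 cells of the library with more than 20% mitochondrial UMIs (10.3% of its cells) and had the lowest median, 1797 UMIs per cell. Jchain, of antibody-secreting cells, stood at 193 CPM in it against 4594 CPM in the B cell class. The pre-B cell class was led by Siglech (2163 CPM) and Ccr9 (936 CPM), genes of plasmacytoid dendritic cells. The T cell class mixed Cd3e (188 CPM), Gzma and Skap1 with the basophil proteases Mcpt8 (748 CPM) and Prss34. With clusters made anew and named by the fixed markers, the share of B cells was 4.00%, with 642 cells of the deposited class in an early B cell cluster, and that of T cells 0, since 282 of the 306 T cell-named cells fell in the 296-cell cluster that scored highest for mast cell and basophil genes.

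Pathway genes differed widely between the classes. The cycling genes Mki67 and Top2a were highest in the Erythroid class, at 2013 CPM (95% Poisson interval 1982 to 2044.5) and 999 CPM. So was the antiviral gene Rsad2, at 873 CPM against 75.2 CPM in the Myeloid class. Of the MHC class II genes, Cd74 was highest in the B cell class (2891 CPM) and H2-Aa in the Macrophage class (1176.5 CPM), and of MHC class I genes, B2m led in the pre-B cell class (2633 CPM) and H2-D1 in the Macrophage class (1078 CPM). Matrix and bone genes stood highest in the MSCs class, Fn1 at 5164 CPM and Spp1 at 2901 CPM, whereas Thbs1 stood at 1773 CPM in the Macrophage class and Cxcr4 at 303 CPM in the B cell class. Macrophages led in the chemokines Cxcl2 (2141 CPM), Ccl6 (879 CPM) and Ccl9 (621 CPM), in Ptgs2, of prostaglandin synthesis (339 CPM), and in Zeb2 (1718 CPM), and the T cell class in Ccl4 (1768 CPM). The Endothelial class led in Vim (1837 CPM), Entpd1 (486 CPM), Nrp1 (303 CPM) and Vegfc (89.5 CPM). Vsir and Cd84 were highest in the Myeloid class, at 361 and 377 CPM, as was Pgk1 at 325 CPM, and Aldoa was highest in the plasma B cell class at 381 CPM. The immediate early genes Fos and Junb were highest in the MSCs class, at 3074 and 3039 CPM. Esr1, the oestrogen receptor, was highest in the B cell class at 99.0 CPM (88.8 to 110.2), then in MSCs at 76.6 CPM, with 18.5 CPM in the Macrophage class, and Pgr was at 4.10 CPM or less in each class.

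The LLC1 panel did not single out a class of tumour cells in this library. It was highest in the Endothelial class, at 1424 CPM (95% Poisson interval 1275 to 1585), almost all of it Tm4sf1 (1389.5 CPM), and next in the MSCs class at 290.1 CPM (260.2 to 322.6). In the other 7 classes it lay between 20.9 and 154 CPM.

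Set beside the sections, the dissociated library held more of the neutrophil genes and less of those of bone, muscle and stroma. Over the 22774 genes in both, 5 of the 27 cell lists stood above the range of the 4 sections, 15 below it and 7 within it. Mature neutrophil genes were at 1.5065e+05 CPM against 26416 ± 14595 CPM in the sections (SD, n = 4), with S100a9 at 64341 CPM against 13551 ± 7144 CPM, and immature neutrophil genes at 42745 against 19959 ± 3107.5 CPM, although Camp, their most abundant member, lay within the sections' range (10755 CPM). The plasma cell list (1181 against 498 ± 150.2 CPM; Igha 848 against 360 ± 130.1 CPM), the monocyte list (1567 against 1381 ± 114 CPM) and the Schwann cell list (104 against 67.6 ± 19.5 CPM) also lay above, though Plac8 (451 CPM) and Pmp22 (11.3 CPM), the members of the monocyte and Schwann cell lists most abundant in the sections, lay below.

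Cells held in bone, muscle and fat were far below the sections. Acta1, of skeletal muscle, stood at 0.321 CPM against 1317 ± 816 CPM, Car3, of fat and muscle, at 0.339 against 225 ± 91.4 CPM, and Col1a1, the bone collagen, at 75.2 against 8901 ± 1702 CPM. Acp5, of osteoclasts, was at 13.2 against 788 ± 80.7 CPM, Cxcl12, of marrow stroma, at 16.0 against 660.1 ± 147.6 CPM, Ppbp, of platelets, at 3.00 against 258 ± 155 CPM, and Plvap, of endothelium, at 4.78 against 59.9 ± 6.35 CPM. Other lists below the range were led by Apoe (macrophage, 133 against 507 ± 121 CPM), Col3a1 (fibroblast, 72.4 against 511 ± 324 CPM), Nkg7 (NK cell, 17.4 against 55.6 ± 18.4 CPM), Vpreb1 (early B cell, 10.9 against 80.5 ± 50.5 CPM), Bst2 (plasmacytoid dendritic cell, 54.8 against 162 ± 33.5 CPM), Mpo (progenitor, 265 against 1103 ± 553 CPM) and Prss34 (basophil, 49.1 against 80.9 ± 9.58 CPM). The dendritic cell list lay below by little, with Flt3 within the range at 9.52 against 9.99 ± 1.86 CPM. The lists within the range were the LLC1 panel (76.1 against 95.2 ± 51.1 CPM; Tm4sf1 below, 14.9 against 44.7 ± 19.1 CPM), chondrocyte (Snorc below, 14.9 against 92.6 ± 56.7 CPM), pericyte (Rgs5 below, 13.6 against 36.2 ± 9.29 CPM), erythroid (Hba-a1 13699 against 16860 ± 5291 CPM), T cell (Trbc2 below, 4.33 against 22.7 ± 13.7 CPM), B cell (Cd79b below, 49.98 against 221 ± 15.6 CPM) and keratinocyte (Krt10 1.46 against 1.32 ± 0.342 CPM). Among the pathway lists, immediate early genes stood at 4945 CPM in the dissociated cells and 237 ± 28.4 CPM in the sections. With 1 dissociated library these are values side by side, and no test was made.

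**Figure D4:**
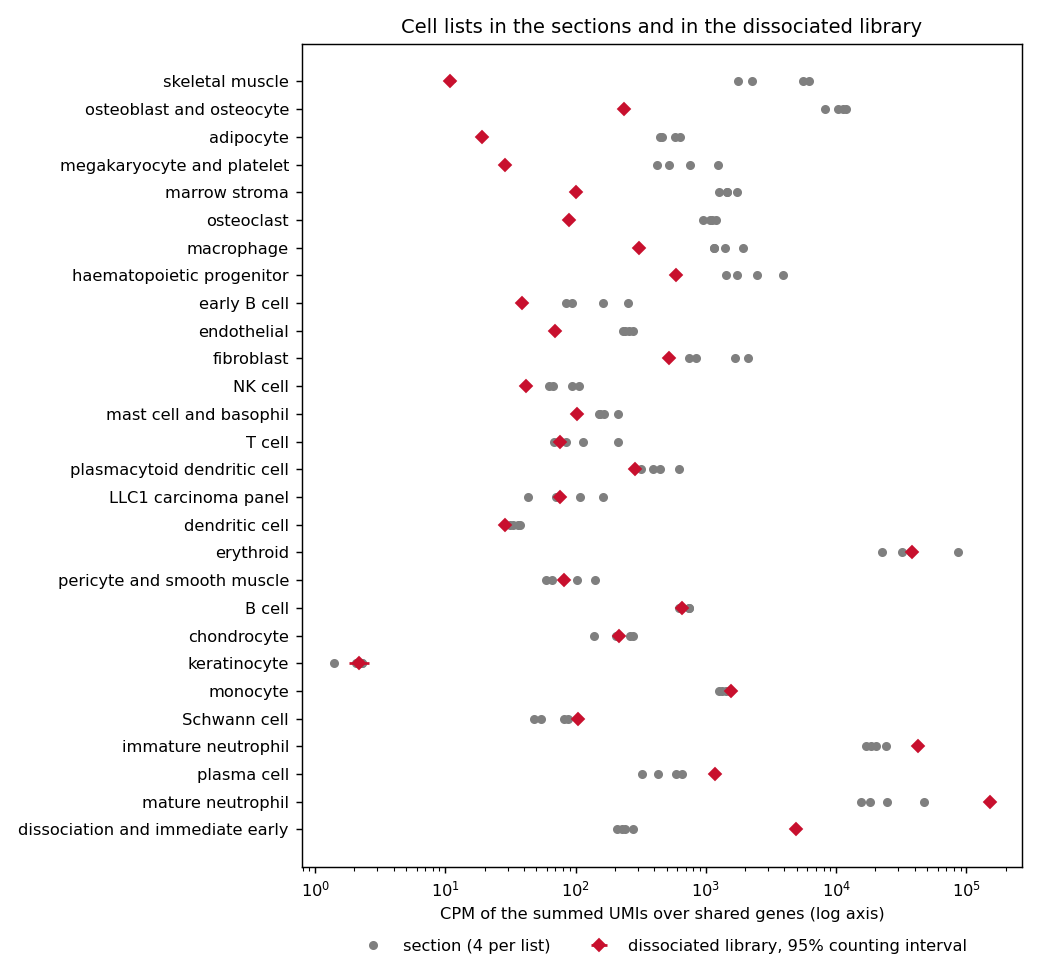
CPM of the 27 cell lists and of the immediate early list over shared genes, on a log axis, in the 4 sections (grey circles) and in the dissociated library (red diamonds with a 95% counting interval, often narrower than the symbol). Muscle, bone, fat and marrow stroma lists lie far to the left of the sections, and neutrophil lists to their right.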

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

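The tests of RNA spread, of the tissue mask and of free RNA below were chosen only after results were seen, whereas those of LLC1 cells among muscle fibres, of mirrored names and of doublets were written before their values were known. Among 47 measures per section, none had a section further from the others than Dixon's 95% bound for 4 samples allows.

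Spots outside the tissue, which no comparison of the report uses, held UMIs: 17816262 in section 2, 12811485 in section 3 and 8748785 in section 4, or 40.2%, 33.9% and 32.0% of all UMIs of these sections. For section 1 only spots over tissue were held. RNA that spread from the tissue could account for these UMIs, since the median at 1 step from the tissue was at least 1.32 times that beyond 10 steps in each section. Yet in section 4 the median at 1 step (1701 UMIs) was under that of all outside spots (1956 UMIs). In section 2 spots beyond 10 steps (3993 UMIs) came close to all outside spots (4071 UMIs). Only section 3 fell clearly with distance (4814 at 1 step, 1120 beyond 10 steps), so spread stays open. Tissue left out of the tissue mask stays open, because up to 48.4% of the outside spots (section 2) held more UMIs than the lower quartile of tissue spots. No biological explanation was tested.

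Tumor-named spots were led by skeletal muscle genes. LLC1 cells among the muscle fibres could underlie the name, yet within cluster 1 the panel's CPM in Tumor-named over Others-named spots was 0.910, 0.571, 2.15 and 0.597 in sections 1 to 4, with a median of 0.754. This median met the result written beforehand as speaking against LLC1 cells, but the ratio spanned values on both sides of 1, with the counting intervals apart in section 4 alone, so the question is left open. Mirroring of the names on the array was tested through the panel at mirrored positions. It reached at most 32.6% of that of cluster 10 (the highest over mirrorings of the median over sections). That summary replaced, after the values were seen, the highest single value, 86.0% in section 4 over 7 positions. The reading of the test, against mirroring, stayed the same. Section 3, however, had 0, 5 and 0 mirrored positions over tissue for rows, columns and both, and section 4 had 4, 7 and 8. In sections 1 and 2, with 18 to 84 positions, the panel reached 8.90% to 45.8% of that of cluster 10. With so few positions in sections 3 and 4, the test cannot make mirroring unlikely over all sections. No biological explanation other than LLC1 cells among the muscle fibres was tested.

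The class deposited as plasma B cell was led by genes of eosinophils and promyelocytes. The class held 111 of the 145 cells with more than 20% mitochondrial UMIs and had the lowest median, 1797 UMIs per cell. Free RNA stays open: Prg2 stood 28.1 times above the next class, but this gene was picked because it leads the class, so its excess decides nothing. Doublets stay open too, with 6.67% of the class among the 5% of cells with the highest Scrublet scores. No biological explanation was tested.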

How the results depend on the processing

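Of the values of named genes under the alternatives, 1952 kept their direction and their side of the threshold, 109 lost their call, 6 gained one, 6 moved and 11 reversed; of the counts and shares, 118 stayed and 39 moved. Where no cause is given below, the cause was not tested.

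In place of the Tumor and Distantial names, panel-high against panel-low spots gave 3332 genes higher and 3163 lower, and the clusters with the highest and lowest panel share 3596 and 3632, against 1936 and 1443. With these clusters log2 fold changes reversed for Cox8b (−0.73), Myh1 (−0.82), Mb (−1.04), Tnni2 (−0.90), Cfd (−0.76) and Hk2 (−0.43), and with panel-high spots for Hk2 (−0.12). Leaving out each section gave 1533 to 2061 higher and 825 to 1269 lower. With the skeletal muscle list left out, chosen after seeing the data, 1853 were higher and 1661 lower.

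Beside Tumor-named spots (901 higher, 103 lower), 488 were higher and 37 lower after thinning, where fewer genes could be tested. The number lower was 26 by DESeq2, 189 with its size factors, 578 with no filter and 44 within 2 and beyond 5 steps, where section 2 also entered. Around panel-high spots 2097 were higher and 1637 lower, and S100a8 (0.14), Igha (0.20) and Jchain (0.057) reversed. Leaving out a section was not possible here, since 1 section leaves no residual degrees of freedom.

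The section is the replicate block of every main fit. With no replicate block, counts of genes higher and lower were 0 and 0 beside Tumor-named spots and 648 and 184 at the panel border, against 2097 and 1637, while the other comparisons stayed within 1.5 times (Tumor-named 1876 and 1116, MSCs-named 2470 and 2081, panel-high 2941 and 2781). Of 202 values of named genes, 50 lost their call with no block. At the panel border, no pooling over neighbours gave 211 higher and 5 lower, and leaving out each section 1383 to 2349 higher and 742 to 1866 lower.

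With an estimated correlation camera called 0 lists in each of the 5 comparisons, and fry called 0 beside Tumor-named spots. Leaving out a section kept 14 to 15 of the 15 lists of Tumor-named spots, 17 to 18 of 18 for MSCs-named spots, 20 to 21 of 22 for panel-high spots and 14 to 16 of 16 at their border, and turned 0.

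Among cells of at least 1000 UMIs, 7.99% were B cell, 55.9% Myeloid and 6.09% plasma B cell. Leiden clusters named by the fixed markers gave B cell 4.00%, Macrophage 4.46%, Myeloid 66.2%, T cell 0%, plasma B cell 0.420% and pre-B cell 4.32%. These hold other cells than the deposited classes: the 648 cells of pre-B cell are an early B cell cluster with 642 B cell-named cells, 236 of the 272 pre-B cell-named cells lie in the plasmacytoid dendritic cluster, and Myeloid takes in the monocyte cluster (679 cells) and the one led by Prg2 and Epx (934). Without the highest 5% of doublet scores, chosen because Scrublet's own bound marked 1 cell, Erythroid was 13.3% and Myeloid 54.9%. The log2 ratio of sections over dissociated cells for Krt10 was −0.15, and 0.082 with haemoglobin, mitochondrial and muscle genes out of the totals.

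Thinned to the smaller sum of each section, 7529 genes in place of 10040 were tested for Tumor-named spots, and 8938 in place of 13372 beside them. In simulated sums a change of 2 times was recovered in 47% of genes for Tumor-named spots, 34% beside them, 78% for MSCs-named spots, 81% for panel-high spots and 76% at their border, and of 4 times in 90%, 77%, 95%, 97% and 97%.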

Other observations

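The MSCs class of the dissociated library held several kinds of cell. Clustered on their own, its 352 cells fell into 9 groups. A group of 66 cells carried pericyte and smooth muscle genes (16803 CPM over the list), one of 30 cells Schwann cell genes (6875 CPM), one of 30 cells osteoblast and osteocyte genes (18233 CPM) and one of 20 cells chondrocyte genes (38364 CPM). Groups of 45, 46 and 52 cells were high in fibroblast genes, at 25944, 26759 and 15956 CPM. A cluster of 63 antibody-secreting cells (Jchain 39488 CPM, Igha 106140 CPM) lay apart from all other cells in the new clustering, and 58 of its cells were named B cell and 5 plasma B cell.

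Cluster 10 of the sections lay where the panel was highest: 60 of its 60 spots in section 1, 82 of 82 in section 2, 75 of 77 in section 3 and 85 of 90 in section 4 were panel-high (the 25% of spots highest in panel share). This overlap was largely set in advance, since cluster 10 was singled out by its panel share and the same panel defines the panel-high spots. Hmga2 also both leads the cluster and belongs to the panel. The overlap therefore says nothing about which cells the cluster holds.

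The tests in this part were all chosen only after results were seen. A hypothesis is that cluster 10 marks LLC1 cells. Depth alone did not bring a high panel share in cluster 6, which reached at most 18.9% of cluster 10's panel CPM. Its spots were about as deep or deeper in sections 1 to 3 and shallower in section 4 (medians of 25323 and 35098 UMIs). That cluster 6 lay below cluster 10 was set in advance, since cluster 10 was picked for the highest panel share. The test therefore cannot exclude depth. The fixed fibroblast, marrow stroma, pericyte and osteoblast lists reached at most 1.015 times their CPM in cluster 3, so cluster 10 held hardly more of this stroma. The panel reached 2.16 to 3.51 times its CPM in cluster 3, but that it was higher was likewise set by the pick. The comparison therefore speaks only of the amount of these lists, and stroma shared with cluster 3 is not excluded. Stroma of another state, such as inflamed stroma, stays open.

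A further hypothesis is that some LLC1 cells sit in the MSCs class. With its cells grouped without the 12 genes that lead cluster 10, a group of 40 cells might be such cells: it held 6236 CPM of those genes (5814 to 6680, 95% Poisson interval), 2.41 times the next group at 2587.5 CPM. In it Myc stood at 1153 CPM and Xist at 215 CPM (143 to 311), against 558 to 1441 CPM of Xist in the other groups. Rhox5 stood at 199.9 CPM, but it is among the 12 genes by which the group was picked, so it adds no support. Xist in cluster 10 was 80.8, 114, 167 and 65.0 CPM in sections 1 to 4. In the Others-named spots it was 85.05, 134, 140 and 119 CPM, so cluster 10 was not lower in section 3. In cluster 1, of muscle genes, it was 65.1, 89.9, 87.9 and 85.2 CPM, below cluster 10 in sections 1 to 3. Among the dissociated cells the Myeloid class stood at 278 CPM of Xist, within the interval of the group of 40. A low Xist level therefore does not by itself mark LLC1 cells. The proliferation list stood at 461 CPM (352 to 594) in the group of 40 and at 697 CPM (486 to 970) in a group of 23 cells. The fixed LLC1 panel stood at 746 CPM (605 to 910) in the group of 40. It was 428 CPM (306 to 582) in the next group, that of Schwann cell genes. Krt8, of the panel, had 0 UMIs in the whole MSCs class, but it reached only 1.46 to 4.06 CPM in cluster 10 of the sections. Of the panel, Hmga2 was 130.7 CPM in the group of 40, from 22.5% of its cells, and 267.3 CPM in the Schwann cell group, from 10% of 30 cells. The group of 40 also carried fibroblast genes (7827 CPM, Dcn 2507 CPM). The group was looked for after the genes had been seen, inflamed fibroblasts remain possible, and Hmga2 (57.1 CPM) and Pvt1 (127 CPM) also lead a cluster of 338 shallow neutrophils.

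Other assignments of the 8 sums to 2 sides were fitted in the same way. They leave the difference between the real sides in the data as spread, which can lower their counts. They therefore cannot tell how often chance alone could give as many genes. Of 35 splits 3 could not be fitted, and among the other 32 only the real split, 1 in each comparison, reached the real count: 3379 genes for Tumor-named spots, 5499 for MSCs-named spots, 6495 for panel-high spots and 3734 at their border. The highest count of any other split was 86 for Tumor-named spots and 0 in the rest. Only 8 splits part both sums of all 4 sections as the real one does, too few for a share under 0.05.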
